A study of Homo sapiens with 7 samples.

How the data were processed

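RNA of the NGP neuroblastoma cell line and of lines derived from it with ARID1A mutations was sequenced in 7 libraries: control cells (2), ARID1A-/- line 1 (2), ARID1A-/- line 2 (2) and an ARID1A+/- line (1). Per the labels' protocols, the first library of each of the 3 replicated groups used the SMARTer Universal Low Input kit for the removal of ribosomal RNA, and their repeats and the ARID1A+/- library used the KAPA mRNA HyperPrep kit. The labels also name polyadenylated RNA as the molecule, so how RNA was selected is uncertain, which bears on histone genes and others whose RNA can lack a poly(A) tail. Both protocols, per the labels, went on with NEBNext Ultra, an average DNA size of 300 bp and single-end reads of 75 bp. The labels do not say whether the libraries of a line came from separate cultures, nor whether reads were counted by strand, so overlapping and antisense genes are uncertain.

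Per the submitters' processing notes, reads were aligned with HISAT2 2.1.0 to hg19; the counting program and the annotation are not given in the sources used here. Per the file headers and values, the authors deposited for each library a table of 28517 named entries with whole-number counts and RPKM values. The deposited RPKM equals the deposited count divided by the entry's length and by the library's total count, to within 0.000501% for every entry with a count above 0, so both columns carry the same data. The entries include gene symbols, long non-coding RNAs, clone names and ribosomal RNA, and those named for ribosomal RNA took between 1.95% and 2.64% of the counts. The total count per library ranged from 24445301 to 43644361.

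The test planned before the data were examined assumed RPKM alone (limma on log2(RPKM + 1)). Because the files also hold counts, edgeR's quasi-likelihood test on the counts, chosen after the files were seen, is the main test; limma on log2(RPKM + 1) was kept as an alternative and DESeq2 was added as one. Entries with a mean RPKM of at least 0.5 over the 6 control and ARID1A-/- libraries were kept (14711). Counts were scaled by TMM with the full library totals. The model held a term for each of the 3 groups and 1 for the kit, which left 2 residual degrees of freedom per gene before the spread was shared across genes. The contrasts were the mean of both ARID1A-/- lines minus control, each line minus control, and line 1 minus line 2. P-values were adjusted by the Benjamini-Hochberg method over all kept genes, with a threshold of 0.05. A standard error is the fitted log2 fold change divided by the square root of its F statistic. Where all libraries of a group were at 0, the fold is a lower bound against a floor of 3 counts over the group, with depth scaled by TMM. For low counts the ratio is given with a 95% exact binomial interval on the summed counts.

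The kit is a batch that the labels name and that is balanced over the 3 groups, so it stood in the main model. Libraries of the same kit also deviated together from their group means: over the 14711 genes the differences between SMARTer and KAPA libraries correlated at 0.51 between control and line 1, 0.63 between control and line 2 and 0.45 between the ARID1A-/- lines. On the log2(RPKM + 1) scale the kit accounted for 25.2% of the variation between the 6 libraries and the groups for 64.0%. The chi-square per gene between the libraries of a group was 130 for the control, 164 for line 1 and 126 for line 2, so no library of a group repeated the counts of the other.

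Gene lists (34) were fixed before the data were examined and tested with edgeR's camera at an inter-gene correlation of 0.01 where at least 3 members were measured (29 lists), with an estimated correlation and with fry as alternatives. No entry matched by symbol the 13 members of the mitochondrial list, nor TIGAR of the p53 targets and HIST2H2AA3 of the histones. Mitochondrial transcripts were among the entries under other names, such as cytochrome b and MTND5, and were not tested as a list. Another 2 lists had 2 measured genes (epithelial and immune markers) and 2 had 0 (endothelial and erythroid markers). Named genes followed a rule fixed beforehand: ARID1A and the BAF subunits, then the 10 largest rises and 10 largest falls past the threshold that had the same sign in 4 of 4 within-kit differences and a mean RPKM of at least 1 in either group. To these came members from among the 4 of each list with the smallest p, not all of which are printed, the 5 genes that differed most in each direction between the lines, and the 5 furthest in each direction from the same-kit control in the ARID1A+/- library. Some genes selected by the rule are not reported here. Loci with systematic names and antisense genes were left out of the ranked parts. Outside the rule, CHGA, NPY, INSM1, PHOX2A, HAND2, GATA3, MYCN, NOTCH1, THBS1, VIM, LGALS1, S100A11, TIMP1, COL1A1, COL1A2, the genes silent in both lines and the gene families of the closing section were chosen after their values were seen. The ARID1A+/- library was compared with the control library of the same kit as a difference of log2(RPKM + 1), with no p-value. List medians were placed among 10000 random lists matched in 20 bins of expression. These lists were drawn gene by gene, so their range leaves out correlation within a list and the spread between libraries.

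Alternatives were limma with pseudocounts of 1, 0.1 and 0.5, no filter and a filter at a mean RPKM of 1, median-of-ratios scaling, quantile normalization, no kit term, no trend and robust estimation. Further ones were DESeq2, the ARID1A-/- libraries as 1 group, and each of the 6 libraries left out in turn. On simulated counts for the contrast of both lines with control (14711 genes, 5 draws, 200 changed genes each, with dispersions as fitted), edgeR recovered 78.0% of genes changed by 1 on the log2 scale and 95.0% of those changed by 2, with at most 39 calls among unchanged genes. In 20 draws without any change the same contrast called at most 19 genes. The camera test was checked on 10 simulated lists of 20 genes raised by 1 and found 10, with 0 calls on unchanged lists. The gene table of the reference held here (RefSeq on GRCh38.p14) is of another build than hg19, so no coordinates are given and it served only for symbols and the order of genes. It matched 13159 of the 14711 tested genes (89.5%), and 1946 of the 2090 genes called in both lines together. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.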

Results

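Gene expression was measured by RNA sequencing in NGP, a human neuroblastoma cell line with amplified MYCN, and in lines derived from it that carry mutations in ARID1A. ARID1A is a DNA-binding subunit of the BAF (SWI/SNF) chromatin remodelling complex. The 7 libraries were 2 of control NGP cells, 2 of ARID1A-/- line 1, 2 of ARID1A-/- line 2 and 1 of a heterozygous ARID1A+/- line. One library of each of the first 3 groups was made with the SMARTer Universal Low Input kit and the repeat with the KAPA mRNA HyperPrep kit, and the ARID1A+/- library was made with KAPA. The total count per library was 43644361, 41401185 and 40724353 in the SMARTer libraries of the control, line 1 and line 2, and 24445301, 31865626 and 28892053 in their KAPA libraries. The ARID1A+/- library held 33032528 counts. The labels do not say that the 2 libraries of a line came from separate cultures, so p-values measure the spread between these libraries, which may be technical. With a single control line, the genotype cannot be separated from other differences between cell lines. Of the 28517 named entries of the deposited tables, 14711 passed the filter on low values and are called genes here.

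ARID1A mRNA was lower in both mutant lines but was still abundant. Its RPKM was 22.3 and 22.0 in the control libraries (SMARTer and KAPA), 16.7 and 17.2 in line 1, 14.2 and 13.8 in line 2 and 19.9 in the ARID1A+/- library. Over both lines it fell by 0.54 ± 0.09 on the log2 scale (SE; edgeR Benjamini-Hochberg adjusted p = 0.012), with line 1 at -0.38 (edgeR adjusted p = 0.066) and line 2 at -0.70 (edgeR adjusted p = 0.009). Its call was lost without either control library (-0.55 without the first, -0.56 without the second) and without the first library (-0.54) or the repeat (-0.55) of line 2. The labels do not give the position of the mutations, so the mRNA level does not check the loss of the protein. Among the 30 measured BAF subunit genes, 2 rose and 4 fell over both lines, ARID1A included. Taken by line, 4 rose and 3 fell in line 1, and 0 rose and 3 fell in line 2. On the mean of both lines SMARCA2, an alternative ATPase of the complex, was higher by 1.17 ± 0.22 and BCL7C by 1.16 ± 0.20, whereas BRD7 fell by 0.60 ± 0.09. The lines differed in SMARCA2 (+1.76 ± 0.24, line 1 minus line 2) and in BRD7 (-0.62 ± 0.11). ARID1B, the paralog of ARID1A, was at +0.44 ± 0.14 and did not pass the threshold (edgeR adjusted p = 0.078). The list as a whole was not called (edgeR camera adjusted p = 0.632).

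**Figure D1:**
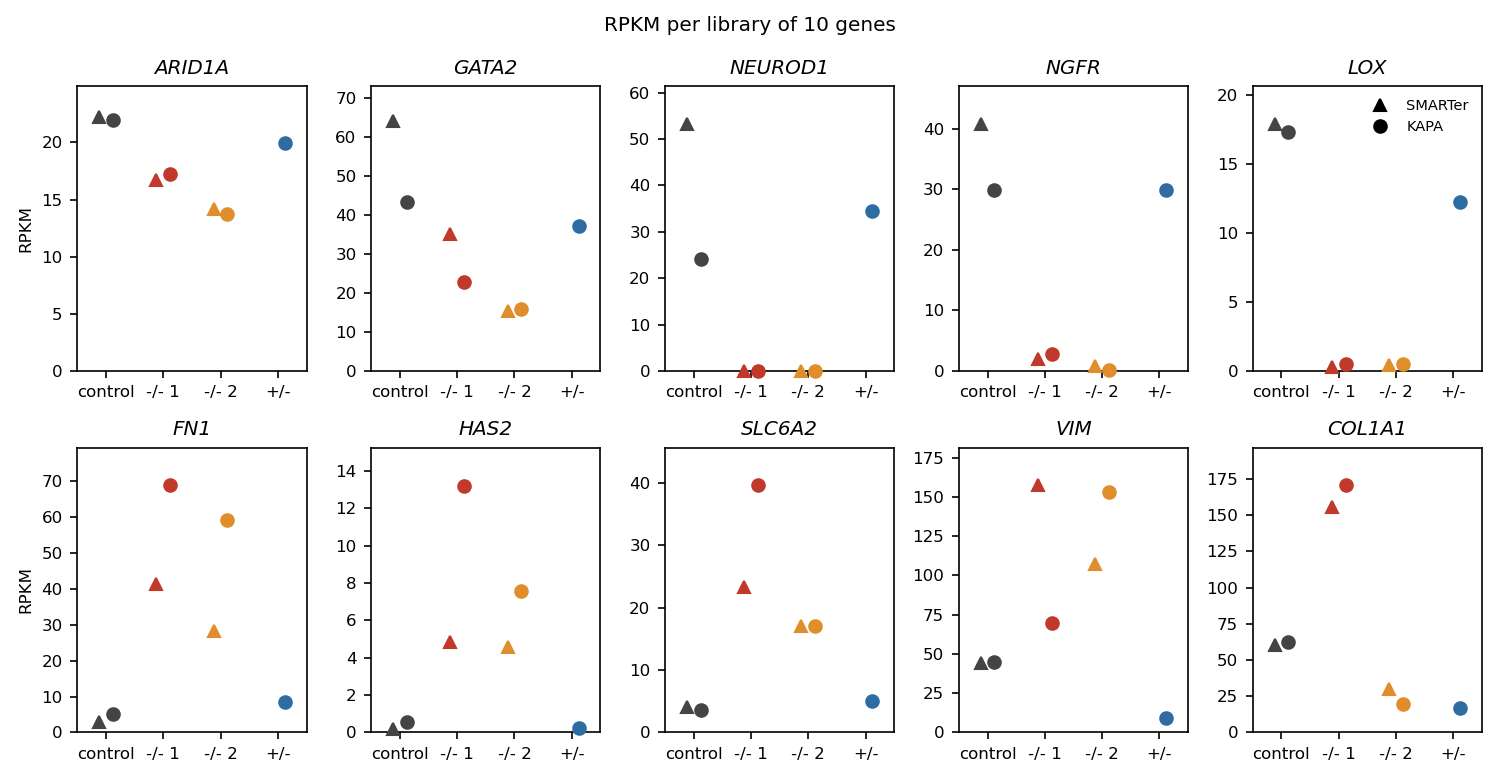
RPKM per library (vertical axis, from 0) of 10 genes in the control, both ARID1A-/- lines (-/- 1 and -/- 2) and the ARID1A+/- line (+/-), with triangles for SMARTer and circles for KAPA libraries. NEUROD1 is at 53.2 and 24.1 in the control, below 0.1 in all 4 ARID1A-/- libraries and at 34.5 in the ARID1A+/- library, while FN1 is at 3.01 and 5.27 in the control and between 28.2 and 68.9 in the ARID1A-/- libraries.

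The series addresses whether loss of ARID1A shifts neuroblastoma cells from an adrenergic to a mesenchymal expression state, and the first comparison took both ARID1A-/- lines against control, as the mean of their log2 fold changes. The adrenergic transcription factor GATA2, which acts in sympathetic neuron development, fell by 1.33 ± 0.16 on the log2 scale (edgeR adjusted p = 0.0031). The matrix protein fibronectin, FN1, rose by 3.54 ± 0.15 on the log2 scale, and the intermediate filament gene VIM rose by 1.44 ± 0.34 (edgeR adjusted p = 0.038). In the opposite sense, the collagen cross-linking enzyme LOX fell by 5.46 ± 0.17 and the noradrenaline transporter SLC6A2 rose by 2.55 ± 0.21. Over all genes 682 rose and 1408 fell (edgeR quasi-likelihood test, adjusted p under 0.05, 2090 genes). Of these, 1900 lay on the same side of the control in all 4 differences taken within a kit.

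The largest falls by the rule fixed beforehand included genes without a single count in any ARID1A-/- library. OCIAD2 was at least 1077-fold lower against a floor of 3 counts over those 4 libraries, the lipoprotein lipase gene LPL at least 629-fold, the cancer-testis antigen gene MAGEA4 at least 547-fold and the embryonic globin gene HBE1 at least 475-fold. HP09025 was at least 459-fold lower and PLAC9 at least 155-fold lower by the same floor. NEUROD1, a neurogenic transcription factor, was 2338-fold lower on 8 counts against 8740 (interval 1186 to 5418). MFNG, a glycosyltransferase that modifies Notch receptors, was 1485-fold lower on 3 counts (interval 508 to 7209), and INHBB, an inhibin subunit, was 655-fold lower on 2 counts (interval 181 to 5420). These intervals and floors cover counting error only.

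The largest rises were of genes that were low in the control. ADCYAP1, which encodes the neuropeptide PACAP, rose by 7.21 ± 0.83 on the log2 scale from 22 control counts. The hyaluronan synthase HAS2 rose by 4.30 ± 0.24, the small proteoglycan decorin, DCN, by 4.38 ± 0.52, the integrin ITGA8 by 4.01 ± 0.61 and the tetraspanin CD9 by 3.83 ± 0.46. LIX1 rose by 4.65 ± 0.50 and the fatty acid oxidation enzyme ECI2 by 4.17 ± 0.23, and the diacylglycerol kinase gene DGKK rose from 28 counts in the control libraries to 963. OR7C1 rose by 5.75 ± 0.55 on 5 control counts and UBTFL1 by 4.02 ± 0.72 on 4. All of these passed the edgeR threshold, with adjusted p between 0.00019 for ECI2 and 0.014 for UBTFL1.

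Of the 23 measured adrenergic transcription factors, 4 rose and 7 fell. Besides GATA2, falls included PBX3 (-0.91 ± 0.13) and INSM1 (-1.21 ± 0.21), while KLF7 (+0.90 ± 0.12) and PHOX2A (+0.54 ± 0.14) rose. HAND2 was at -0.13 ± 0.11 and GATA3 at +0.11 ± 0.11, neither past the threshold. The list was called lower (edgeR camera adjusted p = 0.017), and the p was 0.30 with an estimated correlation. Its median was -0.13, and +0.06 without the repeat of line 2. By line, 5 of the 23 rose and 6 fell in line 1, while 2 rose and 8 fell in line 2. The lines differed in 7 of them, all higher in line 1. The 13 measured genes of catecholamine synthesis and secretory granules held 5 that rose, among them SLC6A2, the granule protein CHGA (1.06 ± 0.19) and the dopa decarboxylase DDC (0.93 ± 0.16), and 2 that fell, GCH1 (-1.92 ± 0.18) and NPY (-1.58 ± 0.41). That list was not called (edgeR camera adjusted p = 0.060). Among the 29 neuronal structure and synapse genes 3 rose and 4 fell (edgeR camera adjusted p = 0.937), with DPYSL3 at -1.43 ± 0.10 and ELAVL4 at +1.18 ± 0.26.

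Mesenchymal genes moved in both directions. Of 19 measured mesenchymal transcription factors 1 rose, ZFP36L1 by 3.67 ± 0.43, and 5 fell, with TBX18 at -1.81 ± 0.19 and SIX4 at -1.54 ± 0.24 (edgeR camera adjusted p = 0.690 for the list). Of 5 EMT transcription factors SNAI2 rose, by 1.73 ± 0.37, and TWIST1 (+0.36 ± 0.14) and ZEB1 (+0.17 ± 0.12) did not pass the threshold (edgeR camera adjusted p = 0.645). Among 25 mesenchymal and EMT effectors 6 rose, including FN1, the growth factor binding protein IGFBP3 (3.39 ± 0.43) and thrombospondin THBS1 (2.75 ± 0.62), and 6 fell, including LOX and tenascin TNC (-3.47 ± 0.41), and the list was not called (edgeR camera adjusted p = 0.847). By line, 8 effectors rose and 3 fell in line 1, while 5 rose and 8 fell in line 2. Collagen and matrix genes were split as evenly on the mean of both lines, 6 up and 6 down of 24 (edgeR camera adjusted p = 0.645). Lumican LUM was at +1.99 ± 0.17, laminin LAMA5 at -3.00 ± 0.13 and nidogen NID1 at -2.83 ± 0.17. In line 1, 7 of the 24 rose and 4 fell, while 4 rose and 7 fell in line 2. The lines differed in 12 of the 24, with 10 higher in line 1 and 2 in line 2. Of 23 integrin and focal adhesion genes 2 rose and 3 fell on the mean of both lines (edgeR camera adjusted p = 0.503). By line, 4 rose and 1 fell in line 1, while 1 rose and 4 fell in line 2. Only 2 of the epithelial markers were measured, EPCAM at -0.53 ± 0.42 and ESRP2 at -0.07 ± 0.19, neither past the threshold.

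**Figure D2:**
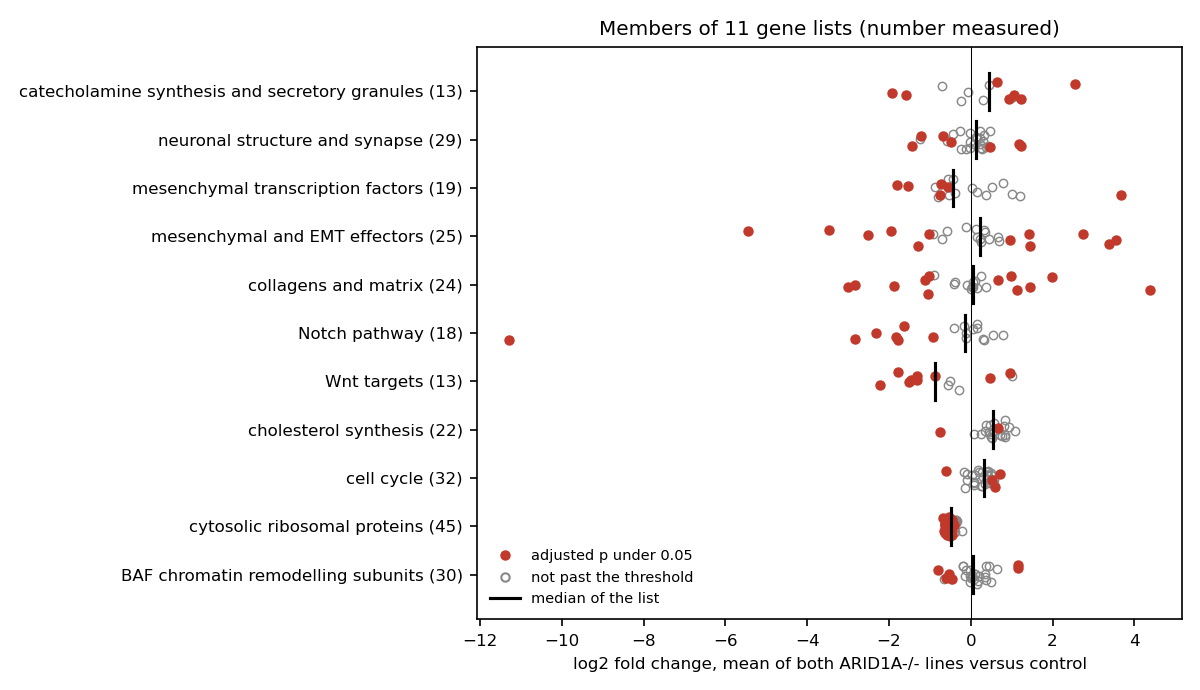
Log2 fold change (mean of both ARID1A-/- lines versus control, horizontal axis) of each measured member of 11 gene lists, with filled points for genes past the adjusted p threshold and a bar at the median. The 45 cytosolic ribosomal proteins lie together around a median of -0.49 (-0.22 after quantile normalization), while the 25 mesenchymal and EMT effectors reach from -5.46 (LOX) to +3.54 (FN1).

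Of 18 measured Notch pathway genes 7 fell, none rose and 11 did not pass the threshold, with a median of -0.14 for the list, and 2 rose in line 1 alone. The falls included MFNG, NOTCH1 (-2.82 ± 0.30), the ligand JAG2 (-1.82 ± 0.19) and the target HES4 (-2.32 ± 0.21). The list's edgeR camera adjusted p was 6.2e-05, its p was 0.21 with an estimated correlation, and the call was lost without the filter on low values and after quantile normalization. Of 13 Wnt targets 7 fell and 2 rose (edgeR camera adjusted p = 0.017, and p = 0.18 with an estimated correlation). The feedback inhibitor NKD1 was at -1.78 ± 0.20, the transcription factor LEF1 at -2.21 ± 0.35 and TCF7 at -1.33 ± 0.17, whereas DKK1, a Wnt antagonist, rose by 0.95 ± 0.16.

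Ribosomal protein genes were lower as a block. All 45 measured cytosolic ribosomal protein genes had a fold change below 0 with a median of -0.49, whereas quantile normalization put 2 of them above 0 and the median at -0.22. Of the 45 genes 29 passed the threshold and 44 did when p was adjusted over the list alone, but 0 passed without either control library or without the replicate block, and 1 without either library of line 2. RPLP2 was at -0.62 ± 0.10 and RPS16 at -0.62 ± 0.11. The edgeR camera adjusted p was 2.3e-10 at the assumed correlation of 0.01, and the p was 0.29 with the estimated correlation of 0.75. Many ribosomal protein genes have near-identical processed pseudogenes with which reads can be shared. The MYC and ribosome biogenesis list held 4 genes that fell and none that rose of 24, among them NPM1 (-0.52 ± 0.12) and TERT (-0.81 ± 0.18), and was not called by the main test (edgeR camera adjusted p = 0.071), though it was by limma.

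The cholesterol synthesis list was called higher (edgeR camera adjusted p = 0.005, and p = 0.45 with an estimated correlation), although of its 22 members only PMVK (+0.67 ± 0.17) rose and STARD4 (-0.76 ± 0.16) fell. Cell cycle genes were called higher with a median of +0.32 (edgeR camera adjusted p = 0.017, and p = 0.58 with an estimated correlation). Of these 32 genes 3 rose on the mean of both lines, MKI67 (0.58 ± 0.13), KIF11 (0.71 ± 0.17) and MCM4 (0.53 ± 0.13), and E2F1 fell (-0.61 ± 0.11). Taken by line, 7 cell cycle genes rose and 1 fell in line 1, while 0 rose and 0 fell in line 2. Their median ranged from +0.05 to +0.54 over 20 settings, the main one included. Markers of other cell types were included because NGP cultures could differ in their makeup. Of 9 fibroblast markers 3 rose (DCN, LUM and COL3A1) and PDGFRB fell (-0.77 ± 0.15), a list called higher (edgeR camera adjusted p = 0.019, and p = 0.10 with an estimated correlation). DCN, LUM and COL3A1 are all also counted among the collagen and matrix genes, a list that was not called. The abundant fibroblast collagen COL1A2 had 0 to 5 counts in every one of the 6 libraries. Of 5 Schwann cell and neural crest markers NGFR (-5.09 ± 0.34) and PMEL (-1.34 ± 0.21) fell on the mean of both lines and none rose (edgeR camera adjusted p = 0.017, and p = 0.093 with an estimated correlation). By line, 2 of these markers rose and 1 fell in line 1, while 0 rose and 3 fell in line 2. The lines differed in 4 of the 5, all higher in line 1. The immune markers LYZ (+0.76 ± 0.37) and CD68 (-0.20 ± 0.20) did not pass the threshold, and no endothelial or erythroid marker passed the filter on low values.

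The other lists were not called by edgeR's camera, with adjusted p given for each. Of 7 drug efflux transporters 2 fell, ABCB1 (-7.70 ± 0.40 on the log2 scale) and ABCC4 (-0.57 ± 0.14; adjusted p = 0.112). Of 9 retinoic acid response genes 2 fell, among them ALDH1A3 (-1.54 ± 0.34; adjusted p = 0.436 for the list). Of 12 AP-1 and immediate early genes EGR1 rose (1.49 ± 0.35) and JUNB (-1.25 ± 0.20) and MYC (-1.34 ± 0.25) fell (adjusted p = 0.775). Of 10 YAP and TEAD targets 2 rose and 4 fell (adjusted p = 0.632), with TEAD1 at +1.05 ± 0.11. Of 17 TGF-beta targets 1 rose and 3 fell (adjusted p = 0.847), SMAD7 among the latter at -1.16 ± 0.24. Of 22 p53 targets 2 rose and 1 fell (adjusted p = 0.847), with TP53I3 at +1.47 ± 0.25. The antigen presentation list had B2M higher by 1.11 ± 0.15 and no other of its 9 genes past the threshold (adjusted p = 0.070). Of 11 interferon response genes IFI6 rose (0.78 ± 0.18) and USP18 fell (-3.25 ± 0.34) on the mean of both lines (adjusted p = 0.937 for the list). By line, 2 of the 11 rose and 0 fell in line 1, while 0 rose and 1 fell in line 2. The lines differed in USP18 (+4.29 ± 0.52, line 1 minus line 2). Of 25 glycolysis and hypoxia genes 3 rose, ADM by 1.80 ± 0.31, and 1 fell (adjusted p = 0.928). Of 22 genes of unfolded protein and amino acid stress SHMT2 fell on the mean of both lines (-0.45 ± 0.10, adjusted p = 0.847 for the list). By line, 4 of the 22 fell and 0 rose in line 1, while 0 fell and 2 rose in line 2. The lines differed in 10 of them, all higher in line 2, SHMT2 included (-1.23 ± 0.12, line 1 minus line 2). Of 12 heat shock genes HSPB1 fell (-1.86 ± 0.19, adjusted p = 0.847 for the list). Of 21 histone genes HIST1H4H rose (1.21 ± 0.26, adjusted p = 0.070 for the list). In all, 8 of the 29 lists that could be tested were called, 3 higher and 5 lower, and 0 of them with an estimated correlation or by fry. The lists with an unadjusted p under 0.05 numbered 12 by camera, 0 with an estimated correlation and 10 by fry. With an estimated correlation the test rests on 2 residual degrees of freedom, so it has little power here.

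When p was adjusted over the list alone, the numbers of genes that rose and fell became 6 and 8 for adrenergic transcription factors, 7 and 3 for catecholamine genes, 5 and 4 for neuronal genes and 4 and 6 for mesenchymal transcription factors. They became 1 and 1 for EMT transcription factors, 9 and 8 for mesenchymal effectors, 7 and 6 for collagens and matrix, 7 and 5 for integrins and 6 and 5 for BAF subunits. For YAP and TEAD targets they were 2 and 5, for Notch 2 and 7, for Wnt targets 3 and 10, for cholesterol synthesis 5 and 1, for glycolysis and hypoxia 3 and 3 and for fibroblast markers 4 and 1. Adjusted over the list alone, 0 histone genes and 0 genes of unfolded protein stress passed, and the other lists kept the numbers given above. The median and the mean differed in sign for the neuronal, mesenchymal effector, collagen, interferon, TGF-beta and heat shock lists, and camera's direction differed from both for the p53 targets.

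The choice of test changed the list calls, though that of the ribosomal proteins was lost only with an estimated correlation and by fry. With limma on log2(RPKM + 1), the test planned at first, the calls of adrenergic transcription factors (limma camera adjusted p = 0.471), Schwann cell markers (0.056) and fibroblast markers (0.067) were lost, and MYC and ribosome biogenesis (0.0036) and histones (0.012) were called. The same calls changed with pseudocounts of 0.1 and 0.5, without the filter on low values and after quantile normalization. In the last 2 settings the Notch call was lost too (edgeR camera adjusted p = 0.131 without the filter, limma camera adjusted p = 0.080 after quantile normalization), and antigen presentation was called in the latter (0.048), where 4 lists were called higher and 3 lower. With the ARID1A-/- libraries as 1 group and the kit term, Schwann cell markers (camera adjusted p by edgeR of 0.155) and fibroblast markers (0.129) were lost, and MYC (0.0068), antigen presentation (0.047) and drug efflux (0.034) were called. A filter at a mean RPKM of 1 ended the Wnt call (edgeR camera adjusted p = 0.083), and without the replicate block antigen presentation and histones were called (0.044 each).

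Single libraries changed the list calls as well, though not that of the ribosomal proteins. Without the first control library 5 lists were called by edgeR's camera, 3 higher and 2 lower. The calls lost were those of Notch (adjusted p = 0.059), Wnt (0.067), adrenergic transcription factors (0.444), cell cycle (0.426), cholesterol synthesis (0.565) and Schwann cell markers (0.066). Those gained were MYC and ribosome biogenesis (0.0029), catecholamine genes (0.019) and histones (0.0047). Without the second control the adrenergic call was lost (edgeR camera adjusted p = 0.147), and antigen presentation (0.0115), p53 targets (0.042) and retinoic acid response (0.018) were called. Adrenergic transcription factors and cell cycle were also lost without the first library of line 1 (edgeR camera adjusted p = 0.534 and 0.12) and without the repeat of line 2 (0.084 and 0.063). Without the first library of line 1, MYC (edgeR camera adjusted p = 0.023), catecholamine (0.032) and histone genes (0.0078) were called. Without its repeat, antigen presentation (edgeR camera adjusted p = 0.029), catecholamine genes (0.029) and drug efflux (0.015) were called, as were catecholamine genes (0.026) and drug efflux (0.025) without the first library of line 2.

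The count of 2090 genes rested on the kit term and on each control library: it was 592 without the replicate block for the kit (109 up and 483 down), 348 without the first control library and 679 without the second, 3570 without the repeat of line 1 and 1278 without the repeat of line 2. When the 4 ARID1A-/- libraries were treated as 1 group, so that differences between the lines counted as spread, 154 genes passed (32 up and 122 down).

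The second comparison took each ARID1A-/- line against control on its own and asked which genes changed the same way in both. In line 1, 699 genes rose and 1217 fell (edgeR, adjusted p under 0.05), and in line 2, 805 rose and 1254 fell. Of these, 247 rose and 558 fell in both lines, and 72 passed in both but in opposite directions. Among the genes changed the same way, 41 rose and 241 fell by more than 4-fold on the mean of the lines. NEUROD1, LOX, ABCB1 and LAMA5 were lower in both lines and FN1, HAS2 and ITGA8 higher in both. Collagen COL1A1, chosen after its values were seen, passed in opposite directions: it was at RPKM 60.2 and 62.6 in the control, 156 and 171 in line 1 and 30.3 and 19.9 in line 2. Lists of these sizes drawn independently would share 38.2 genes that rose and 103.7 that fell. Groups simulated without any effect against the same controls shared 0.45 genes on average (20 draws, at most 3). In these draws line 1 and line 2 had at most 17 and 9 calls. The simulation therefore cannot show how much the shared controls add to the overlap of lists as long as the real ones. Both lines share their controls, which could not be split because each part would hold 1 library. The count of 805 genes was 202 without the replicate block, 160 without the first control, 273 without the second, 1513 without the repeat of line 1 and 436 without that of line 2. The counts for line 1 and line 2 were 475 and 519 without the block, 436 and 408 without the first control, and 592 and 758 without the second. Without the repeat of line 1 they were 3028 and 3738, and line 2 also moved to 3631 without the first library of line 1, to 1067 without its own first library and to 772 without its repeat.

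Across the 14711 genes, the log2(RPKM + 1) differences of both lines from control had a Pearson r of 0.55 and a Spearman rho of 0.47, where genes are not independent replicates. Because both lines were compared with the same controls, unchanged simulated groups gave a mean r of 0.50, while the covariance was 0.143 in the data and 0.0216 in the simulation, a difference of 0.121. Differences that share no library had an r of 0.49 (line 1 in SMARTer, line 2 in KAPA) and 0.36 (line 1 in KAPA, line 2 in SMARTer). Within a line, the SMARTer and KAPA differences had an r of 0.70 for line 1 and 0.77 for line 2.

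**Figure D3:**
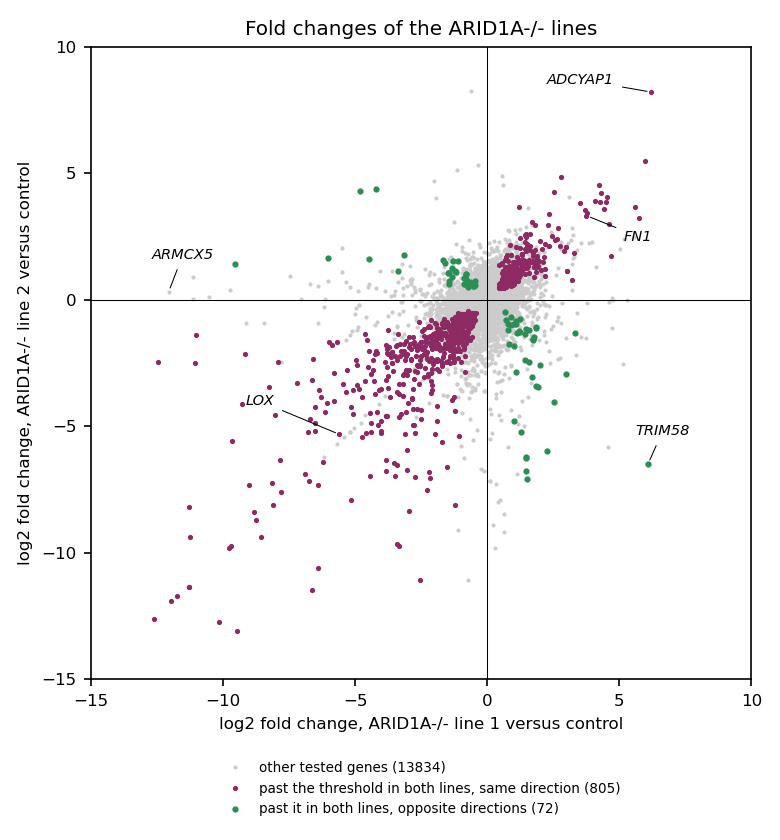
Log2 fold change against control of each of the 14711 tested genes in ARID1A-/- line 1 (horizontal axis) and line 2 (vertical axis), with genes past the threshold in both lines coloured by whether the directions were the same (805) or opposite (72). LOX, FN1 and ADCYAP1 lie in the quadrants of shared direction, while ARMCX5 and TRIM58 lie far from the diagonal.

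The third comparison set the ARID1A-/- lines against each other, and many genes were present in one and missing from the other. ARMCX5, MAP10, AFF2 and SLITRK1 had 0 counts in both libraries of line 1 and 1348, 575, 1121 and 427 in those of line 2, and SPIN3 had 1 against 2460. In the other direction TRIM58, HDHD3 and RDM1 had 0 counts in line 2 and 1539, 324 and 140 in line 1, while TRIM21, an antibody receptor and ubiquitin ligase, had 2 against 2005 and EFS had 4 against 2355. Of the 25 mesenchymal and EMT effectors 8 differed: 6 were higher in line 1, among them S100A11, TIMP1 and LGALS1 by 6.49 ± 0.39, 6.63 ± 0.66 and 3.92 ± 0.39 on the log2 scale, and 2 were higher in line 2, TNC (-3.80 ± 0.59, line 1 minus line 2) and IGFBP3 (-1.75 ± 0.41). In total 840 genes were higher in line 1 and 1045 in line 2 (edgeR, adjusted p under 0.05, 1885 genes). Of the 21 measured histone genes, whose RNA mostly lacks a poly(A) tail and depends on how RNA was selected, 14 differed, all higher in line 1. The count was 404 without the replicate block, 1227 without the first control library, 819 without the first library of line 2 and 772 without its repeat.

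The fourth comparison placed the ARID1A+/- line, which has 1 library and therefore no replicate check, against the control library of the same kit. The POU-domain transcription factor POU4F1 stood at RPKM 96.3 against 7.38 and the gap junction gene GJA1 at 33.1 against 1.12. HCLS1 was at 24.5 against 0.186, ADCYAP1 at 16.5 against 0.0242 and IGFBP3 at 23.6 against 1.27. Lower values were found for MFNG (0.0425 against 18.1), DPP7 (0.449 against 20.6), ARHGAP36 (5.76 against 84.4), NMU (0.0371 against 11.4) and MAGEA3 (1.40 against 27.7). On the log2(RPKM + 1) scale 338 genes were at least 2-fold higher and 379 at least 2-fold lower among 13723 with an RPKM of 1 in either library. By the same rule the KAPA libraries of line 1 and line 2 gave 361 and 367 higher and 578 and 626 lower. With a pseudocount of 0.1 the ARID1A+/- library gave 576 higher and 664 lower, and with median-of-ratios scaling 368 higher and 360 lower.

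The 322 genes that were at least 2-fold lower in both lines among the SMARTer libraries, which share no library with this comparison, had a median difference of +0.04 in the ARID1A+/- library, against -1.24 and -1.38 in the KAPA libraries of line 1 and line 2. The 81 genes that were at least 2-fold higher had a median of +0.02, against +0.96 and +1.47. Of the lower genes 53 were at least 2-fold lower in the ARID1A+/- library too, 16.5%, and of the higher genes 7 were at least 2-fold higher, 8.64%. Both shares were above those over all genes, where 379 were at least 2-fold lower and 338 at least 2-fold higher of 13723. By direction alone, 155 of the 322 lower genes were below the control (48.1%) and 43 of the 81 higher genes above it (53.1%). How many moved 2-fold the opposite way was not counted, so the shares do not show a shared direction. ABCB1 was at 10.4 against 21.7, and NEUROD1 (34.5 against 24.1), NGFR (30.0 against 29.8) and SLC6A2 (4.97 against 3.66) were near the control. VIM was at 9.34 against 44.5 and COL1A1 at 17.1 against 62.6, both below control. Ribosomal protein genes had a median difference in the ARID1A+/- library of -0.03, at percentile 58.2 among 10000 random lists matched on expression. The medians of 12 of the 29 lists lay above the middle 95% of matched lists and those of 4 below it. That range leaves out correlation within a list and the spread between libraries, so it is too narrow for a test. The percentiles only describe this 1 library. The mesenchymal and EMT effectors had a median of +0.26, above all matched lists, with 5 of the 25 genes at least 2-fold higher and 2 at least 2-fold lower, the EMT transcription factors one of +0.36 at percentile 99.12 and the adrenergic transcription factors one of +0.11 at percentile 98.47. The fibroblast markers had a median of +1.32, above all matched lists, LUM being at 13.7 against 1.72 and COL1A2 at 6 counts. The collagen and matrix list had a median of +0.26 at percentile 99.98, and the catecholamine list one of +0.30 at percentile 99.94. The neuronal list was at -0.21, percentile 0.09, and the MYC and ribosome biogenesis list at -0.25, below all matched lists.

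A set of genes without detectable or with very low expression in both ARID1A-/- lines, defined after the data were seen, was compared with the ARID1A+/- library. Of 11722 genes with a RefSeq symbol and an RPKM of at least 1 in both control libraries, 30 were below 5% of the same-kit control in all 4 ARID1A-/- libraries, while 43 were so in line 1 alone and 51 in line 2 alone. In the reverse direction, 2 of 11003 genes with an RPKM of at least 1 in all 4 ARID1A-/- libraries were below 5% of them in both controls. The ARID1A+/- library was below 5% of the same-kit control for 8 of the 30 genes, or 26.7% (exact 95% interval 12.3% to 45.9%), and for 10 of the 94 genes silent in a single line, or 10.6% (interval 5.22% to 18.7%). Over all 11722 genes it was so for 55, or 0.469%. Genes at 50% of control or more in the ARID1A+/- library included NEUROD1, OCIAD2 (58.4 against 30.8) and LOX (12.2 against 17.3), whereas MFNG, LPL and MAGEA4 were absent or below 0.1 there as well.

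**Figure D4:**
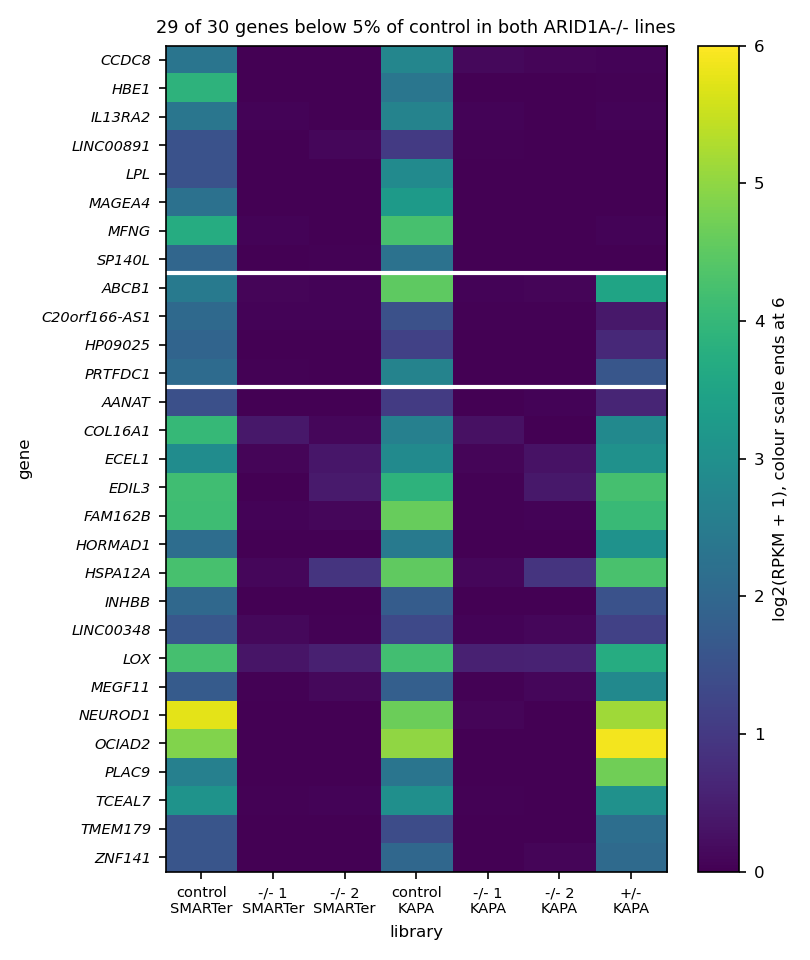
Expression as log2(RPKM + 1) (colour) of 29 of the 30 genes that were below 5% of control in both ARID1A-/- lines, 1 gene per line of the map and 1 library per column. White lines part the 8 genes also below 5% of control in the ARID1A+/- library (top), 4 between that limit and 50% of control (middle) and 17 at 50% or more (bottom).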

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

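Both tests below were set before their results were seen. The ARID1A-/- lines differed from each other in 1885 genes by the contrast of line 1 minus line 2 (edgeR, adjusted p under 0.05), which tests the difference itself and is what set apart every result here. Of the 127 genes named in the text, 39 differed, 25 of them higher in line 1 and 14 higher in line 2. The log2 differences (line 1 minus line 2) above 2 were TRIM58 (12.57), HDHD3 (10.36), TRIM21 (9.81), EFS (9.09), RDM1 (9.08), TIMP1 (6.63), S100A11 (6.49), USP18 (4.29), LGALS1 (3.92), UBTFL1 (3.09), COL1A1 (2.76), NGFR (2.5), LUM (2.41), COL3A1 (2.36) and PMEL (2.25). Those between 0 and 2 were LIX1 (1.93), DPP7 (1.87), SMARCA2 (1.76), EPHB3 (1.58), ARHGAP36 (1.57), DDC (1.21), HSPB1 (1.17), POU4F1 (1.15), SLC6A2 (0.90) and GATA2 (0.89). The genes higher in line 2 were ARMCX5 (-12.38), AFF2 (-12.05), MAP10 (-11.15), SPIN3 (-10.98), SLITRK1 (-10.65), TNC (-3.80), EPHA5 (-3.70), NMU (-3.45), CD9 (-2.06), IGFBP3 (-1.75), NID1 (-1.54), SHMT2 (-1.23), STARD4 (-1.12) and BRD7 (-0.62). Where a line had 0 counts, the fitted difference depends on the prior count and is no bound.

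The difference between the lines was weighed against copy number and detection. Copy number differences that span most of the 50 surrounding genes were argued against as the whole cause. After subtracting the median difference of the 50 surrounding tested genes, the called genes kept a median share of 0.96 of their difference (bootstrap interval 0.953 to 0.969, 1658 genes). A median over 50 genes cannot register the loss or gain of a single gene, or of a segment that covers only a minority of them. Some regions did shift as blocks, as 25 of 252 windows of 50 genes lay beyond a limit of 0.21 on the log2 scale that chance would exceed in 0.252 windows, the largest at 0.90. As for detection, 80.5% of the called genes had a mean RPKM of at least 2 in the higher line (exact interval 78.6% to 82.2%). Most called genes were thus above that level in 1 of the lines. The filter on low values favours such a level, and the share over all tested genes and the lower line were not examined. The test therefore cannot decide on a role of the detection floor. What stays open and was not tested is loss or gain of single genes or of such shorter segments, variation between the lines apart from ARID1A, or different mutations in each.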

How the results depend on the processing

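The main test (edgeR on counts) and DESeq2 were tests chosen only after the data were seen, whereas limma on log2(RPKM + 1) was planned as the main test and became an alternative then. Of 114 values for counts of genes or lists and for the correlation, 80 stayed within 1.5 times the main value (within 0.1 for the correlation), and no called gene was called in the opposite direction. In each comparison of the ARID1A-/- lines more genes fell than rose in every setting (for line 1 against line 2, more were higher in line 2). The lists called, 5 lower and 3 higher, became 3 higher and 2 lower without the first control library and 4 higher and 3 lower after quantile normalization. The ARID1A+/- library, with 338 genes higher and 379 lower, had 368 higher and 360 lower with median-of-ratios scaling.

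Without the replicate block for the kit the number of genes called fell from 2090 to 592 for both lines (share that rose 18.4% against 32.6%), from 1916 to 475 for line 1, from 2059 to 519 for line 2, from 1885 to 404 for line 1 against line 2 and from 805 to 202 for genes changed the same way.

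Taking the ARID1A-/- libraries as 1 group gave 154 genes with the kit term (20.8% rose) and 162 without it (15.4% rose), since differences between the lines then count as spread. Without the filter on low values, both lines together gave 3147 and genes changed the same way 1300; the cause was not tested. With 1 library left out, where the lone library of a group is assumed to vary like the others, the counts ranged from 348 to 3570 for both lines, 436 to 3028 for line 1, 408 to 3738 for line 2, 772 to 2407 for line 1 against line 2, 160 to 1513 for genes changed the same way and 5 to 11 for lists. The lowest were without the first control library, except for line 1 against line 2 (without the repeat of line 2), and the highest were without the repeat of line 1; the cause was not tested. Of the 8 list calls 0 held with an estimated correlation and 0 by fry. The test with an estimated correlation rests on 2 residual degrees of freedom and has little power. A call lost there does not by itself show that correlation between genes had made it. The estimated correlation was 0.75 for ribosomal proteins, 0.83 for cell cycle, 0.75 for cholesterol synthesis and 0.38 for Notch. It was 0.19 for adrenergic transcription factors and 0.11 for Wnt targets. All of these lie above the 0.01 of the main test, so a part of correlation in these calls stays open. For the Schwann cell and fibroblast markers the estimated correlation was negative (-0.18 and -0.10). Their unadjusted camera p still went from 0.0029 to 0.093 and from 0.0053 to 0.10. The correlation of the lines moved from 0.55 to 0.36 for line 1 in KAPA and line 2 in SMARTer, and the ARID1A+/- count moved from 717 to 1240 with a pseudocount of 0.1, which widens differences of low genes. limma on log2(RPKM + 1) called 1651 genes for both lines and DESeq2 2617, both within 1.5 times.

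ARID1A stayed between -0.56 and -0.50 over 21 settings and lost its call in 7. For the 125 genes traced over both lines, 2105 of 2609 values kept their side of the threshold, 464 lost the call, 17 gained one, 20 moved among the libraries of 1 kit and 3 changed sign. For 14 genes of line 1 against line 2, 229 of 233 kept it, and for the 29 lists 441 of 522 did, with 49 calls lost and 32 gained. EPHA5 moved to +0.019 after quantile normalization and S100A11 to +0.30 and +0.21 with the ARID1A-/- libraries as 1 group, with and without the kit term, where the lines' own means (far apart for this gene) are merged; the cause was otherwise not tested. Depth limits the genes at 0 counts to lower bounds.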

Other observations

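The tests on overlap and on the ARID1A+/- line for the silent genes, those on the KAPA libraries alone, on close pairs and on TOP mRNAs, and the gene families, were chosen only after the results were seen. Clustered protocadherins are adhesion proteins expressed in combinations on neurons. All 22 measured gamma protocadherins rose over both ARID1A-/- lines (edgeR adjusted p under 0.05), with a median log2 fold change of +1.01, and all 15 alpha protocadherins rose with a median of +0.70. Genes within each of these clusters share constant exons, so reads can be counted for all of them and the members are not independent. Their fold changes spanned 0.93 to 1.12 for gamma and 0.61 to 0.73 for alpha. Of the beta protocadherins, which lack such shared exons, 4 of 16 rose, 0 fell, and 10 (62.5%) had a fold change above 0 in both lines. That share was also weighed against reads from shared exons, left the matter undecided, and was then dropped in favour of the patterns below. In the ARID1A+/- library the gamma, alpha and beta medians were +1.09, +0.66 and +0.21.

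Other gene families, not tested as groups, moved in either direction over both lines. Of 6 GABA receptor genes 3 rose and 1 fell (median +0.41), of 19 HOX entries 3 rose and 3 fell (median +0.15), and of 14 SNHG genes 6 fell and 0 rose (median -0.39). Of 8 measured MAGEA and MAGEC cancer-testis antigen genes 6 fell and 0 rose, with a median of -2.40, though their sequences are close enough for reads to be shared. Of 11 RGS genes, regulators of G-protein signalling, 7 fell and RGS2 rose. The semaphorin receptors PLXNB1, PLXNB2, PLXNC1 and PLXND1 fell (4 of 8 plexins, 0 rose). The ephrin receptors EPHA5, EPHA8, EPHB2 and EPHB3 fell (4 of 7, 0 rose), though EPHA5 was at +0.02 after quantile normalization. All 6 measured SRGAP genes fell, several of which are close copies of SRGAP2 that can share reads. MYCN was at RPKM 3663 and 1226 in the control, 1435 and 1063 in line 1, 2343 and 606 in line 2 and 783 in the ARID1A+/- library, and its change of -0.78 ± 0.27 did not pass the threshold (edgeR adjusted p = 0.109).

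For the 30 genes silent in both ARID1A-/- lines, chance overlap of independent losses was argued against: 45 genes were silent in line 1 by its SMARTer pair and in line 2 by its KAPA pair, which share no library, against at most 8 in 10000 draws matched on expression (mean 1.59). Loss common to every edited line cannot be told apart from loss tied to ARID1A-/-, as the ARID1A+/- line has 1 library: it lacked 26.7% of the 30 genes (exact interval 12.3% to 45.9%). The set was narrowed to genes with a RefSeq symbol after that result was seen; over all 45 entries silent in both lines, 15 without such a symbol included, the share was 44.4% (interval 29.6% to 60.0%), and at a limit of 25% of control, the first one planned, it was 33.3% of the 30. Deletion of segments cannot be told apart from loss of single genes, since the nearest neighbours (58 genes) had a median log2 fold change of -0.15 with a bootstrap interval of -0.33 to -0.04, between the bounds set beforehand for deletion (-0.5) and against it (-0.25). A dependence on ARID1A stays open as a hypothesis, as do differences between cell lines unrelated to it, and 0 of the silent genes were neighbours of each other.

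The fall of ribosomal protein genes, with a median of -0.49, was argued not to be a trait of short, abundant transcripts, since 45 other genes matched on length and control RPKM had a median of -0.093 (bootstrap interval -0.15 to -0.02), and although these were longer (median length 1484 against 1180) and less abundant (control RPKM 480 against 665), the 32 pairs within 0.5 log2 units on both had medians of -0.09 (interval -0.17 to -0.01) for the matched and -0.49 for the ribosomal genes. It was not carried by the first control library alone, as 44 of the 45 genes were lower in both lines than in the control among the KAPA libraries, with medians of -0.36 in KAPA and -0.64 in SMARTer. A hypothesis from these values is that mRNAs with a 5-prime TOP motif fell together: 15 of them outside the ribosomal protein list, among them EEF1D (-0.72 ± 0.10) and TPT1 (-0.75 ± 0.14), had a median of -0.51, below the 2.5th percentile of matched random lists (-0.28), with 6 past the edgeR threshold, and the 10 translation factors among them had one of -0.52 (percentile 0.01) with 4 past it, the other 5 being of mixed function, a ribosomal protein gene included. Under quantile normalization, which forces the libraries to a common distribution, their median was -0.28, and without either control library 0 (first) and 1 (second) of the 15 passed. The matched random lists leave out correlation between genes, so the percentiles of the TOP mRNAs are descriptive only. For the 13 ribosomal genes without a close match in length and abundance, the effect of these stays open. Reads shared with pseudogenes and a difference in growth state at harvest stay open too and were not tested.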
